A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

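Chromatin immunoprecipitation on microarrays (ChIP-chip) was used to map where MYC-tagged proteins associate with the genome of haploid budding yeast of the W303a background. The cells were growing asynchronously in rich medium at an optical density of 0.25, per the labels. The tagged proteins were DNA Pol2, the catalytic subunit of DNA polymerase epsilon, and Rrm3, a DNA helicase. On each of 16 two-colour arrays, DNA recovered with a MYC antibody (the IP) was hybridised with total genomic DNA (the input) from fixed cells. The spots were PCR products of open reading frames (ORFs) and of the regions between them. Per the labels the input carried Cy3 and the IP Cy5, and the dyes were exchanged on arrays called dye swaps.

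Each array came as scanner output with deposited intensity values per spot, namely the median signal and the median local background in each channel, together with a quality flag and a record of failed PCR products. The authors' series text states that log2 ratios of IP over input were normalised on the median and averaged, and the deposited value table holds 1 log2 column per array. The scanner, the spot-finding software and the genome build are not given in the sources used here. Set against the scanner values, the deposited log2 columns followed the logarithm of the ratio of background-subtracted medians with a correlation of at least 0.999 in size on every array. Dye-swapped arrays and array 136 had been turned, so that all columns read IP over input if the turn of array 136 was right. The medians of the deposited columns lay between -0.05 and 0.09 except for array 031, at -0.46, so centring was close to but not exactly 0.

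For the values given here, background-subtracted channel medians were used as deposited. Spots with a quality flag or with a signal at or below 0 in either channel were left out. Log2 ratios of IP over input were averaged over spots of the same name and centred on the median of each array, without loess or quantile normalisation, because real association can shift many features 1 way. Features measured on at least 3 arrays of every group were tested, 12350 of 13025 names. The arrays followed a layout of 13060 names, except arrays 031 and 041, whose layout held 15356. Names found only on that second layout were not analysed here. Of 6210 ORF names, 5679 matched a locus tag of the R64 reference table, which was used for symbols and for the order of genes only. No coordinates are given because the build is not known. No 2 arrays held identical values.

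Groups were taken from the labels: 4 arrays of the Pol2 IP in wild type, 6 of the Pol2 IP labelled rrm3 delete and 5 of the Rrm3 IP. The labels of array 231 contradict each other on the deletion, so it entered no comparison. Array 136 was labelled as carrying the IP in Cy5, but its ratio then correlated negatively with every other array, from -0.54 to -0.15 across features. No pair of the other grouped arrays correlated below -0.13. These values argue against the labelled direction, but the label and the deposited table still disagree. The direction of the deposited table was used, which also places array 136 among the dye swaps in the dye term and leaves it out of the alternative with forward arrays alone. The counts with the labelled direction, and the list calls that change with it, are given with each comparison. The series text calls the dye swaps technical replicates without saying which arrays share an extract. The number of arrays is therefore not the number of cultures, and p-values measure the spread between arrays, which may be smaller than that between cultures.

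A single linear model was fitted to all 15 grouped arrays with limma 3.58.1 in R 4.3.3, with a mean per group and a dye term per feature, followed by empirical Bayes moderation of the variance (prior degrees of freedom 6.14). Each group mean was tested against 0, the array median, and 2 differences were tested: arrays labelled rrm3 delete minus wild type, and Rrm3 IP minus wild-type Pol2 IP. Both differences share the 4 wild-type arrays. P-values were two-sided and adjusted by the Benjamini-Hochberg method over features, with a threshold of 0.05, and errors of fitted values are standard errors (SE). A feature's n is the number of arrays that measured it.

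Feature lists were tested against all other features with limma's camera procedure at a preset correlation of 0.01 between features, over 23 lists and 5 contrasts with Benjamini-Hochberg adjustment over the 115 pairs. The same test was repeated with an estimated correlation (median 0.111). Only that correlation was estimated over 13 arrays, without arrays 136 and 182. It used list members measured on all of these arrays. Those were 3 silent mating locus ORFs, 4 centromere features, 5 telomere features and 5 cell surface protein genes, so the estimated test decides little for these lists. The statistics tested came from the fit to all grouped arrays, with arrays 136 and 182 included. The 18 lists fixed before the data were examined were genes of glycolysis and fermentation, translation factors, histones, chaperones, cell surface proteins, galactose use, meiosis and sporulation, ribosomal proteins, the silent mating loci, subtelomeric ORFs, all ORFs, and features named as tRNA genes, centromeres, rDNA, LTR and Ty elements, snRNA and snoRNA genes, mitochondrial DNA and intergenic regions. Subtelomeric ORFs were redefined as the 8 outermost protein-coding genes of each chromosome end. Lists of replication origins and of the 2-micron plasmid had no measured members. A further 5 lists were added after the data were seen: regions beside tRNA genes, ORFs next to a tRNA gene, regions beside centromeres, telomere features, and the ORFs and regions with the 8 highest systematic numbers of each chromosome arm. Median, mean and test of a list differed in sign in 10 of the 115 pairs, of which 0 passed the threshold.

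The rule for named features, set before the data were examined, took in each contrast the 10 with the largest positive value (for differences also the 10 most negative) among those past the threshold with the same sign on every array, or with groups that did not overlap. It also took the 3 members of each list with the smallest adjusted p, and RRM3 and POL2 on every array. Tests on single list medians per array were exact two-sided permutation tests.

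Alternatives fixed beforehand were other background corrections, loess, no dye term, forward arrays alone, stricter and absent spot filters, the deposited table, another variance model, an added 1.5-fold minimum and leaving out each array. Those added after the data were seen were array 136 as labelled, arrays 136 and 182 or 031 and 041 left out, failed PCR products left out and the deposited table without centring. A block for scan or print batch was not run because the files name no batch.

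The procedure was tested on simulated data with the fitted spread of each feature, taken as equal on all arrays. Of 12350 features, 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. A further 41 features were shifted by 0.5 as a list and counted as true where called. The noise was independent between features and arrays. Real features correlate and dye swaps may share an extract. Real arrays also differ in spread: the SD of log2 ratios over features was 0.45 on array 039 and 1.03 on array 031. The rates may therefore differ on the real arrays. A change of 0.5 on the log2 scale was recovered for 16.4% of features in wild type, 22.4% in arrays labelled rrm3 delete, 10.4% in the Rrm3 IP, 0% for the difference between the Pol2 groups and 1.49% for Rrm3 minus wild-type Pol2. A change of 1 was recovered for 70.1%, 92.5%, 82.1%, 35.8% and 19.4% in the same order, and a change of 2 for 100%, 100%, 100%, 93.9% and 100%. Between 2.27% and 8.43% of calls were false. The number of arrays limits the precision.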

Results

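The series set out to map sites where replication forks pause in the budding yeast genome, using DNA polymerase epsilon (tagged on Pol2) and the Rrm3 helicase, an enzyme known to help forks past tightly bound proteins. IP over input was measured in wild-type cells for Pol2 (4 arrays: 039, 086, 136 and 230) and for Rrm3 (5 arrays: 031, 041, 088, 184 and 185), and for Pol2 on 6 arrays labelled rrm3 delete (040, 137, 182, 183, 239 and 240). Between 6255 and 12871 features were measured per array, the lowest numbers on arrays 182 and 136, where 54.0% and 49.7% of spots carried a quality flag. Across features, pairs of arrays correlated with a median r of 0.37 within wild type, 0.52 within the arrays labelled rrm3 delete and 0.22 within the Rrm3 IP. Between groups it was 0.41 for wild type with arrays labelled rrm3 delete, 0.24 for wild type with the Rrm3 IP and 0.20 for the remaining pairing. Wild-type and Rrm3 arrays thus resembled their own group no more than another. Arrays 182 and 184, dye swaps of different groups, correlated at 0.68. Arrays 182 and 137, of the same group but opposite orientation, correlated at 0.04. The extraction text of wild-type array 086 names an antibody to a histone mark as well as the MYC antibody, so what was precipitated there is not settled, and its other labels place it with the Pol2 IP. Array 031 correlated with the other arrays at -0.07 to 0.23.

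The RRM3 feature itself was examined first, because a deletion of the probed part would remove its signal. The percentile of its input signal among all spots was 1.60 to 11.97 on 5 of the 6 arrays labelled rrm3 delete, against 32.7 to 90.4 in wild type and 32.1 to 94.8 in the Rrm3 IP. On array 239, also labelled rrm3 delete, it was 50.1 in the input and 48.1 in the IP, which goes against that label. The group is therefore called "arrays labelled rrm3 delete" throughout. How much of the gene was deleted is not given in the sources used here. The POL2 feature lay near the array median in all groups, at log2 0.12 ± 0.18 (SE, n = 4) in wild type, -0.07 ± 0.16 (SE, n = 5) on arrays labelled rrm3 delete and 0.15 ± 0.16 (SE, n = 5) in the Rrm3 IP.

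**Figure D1:**
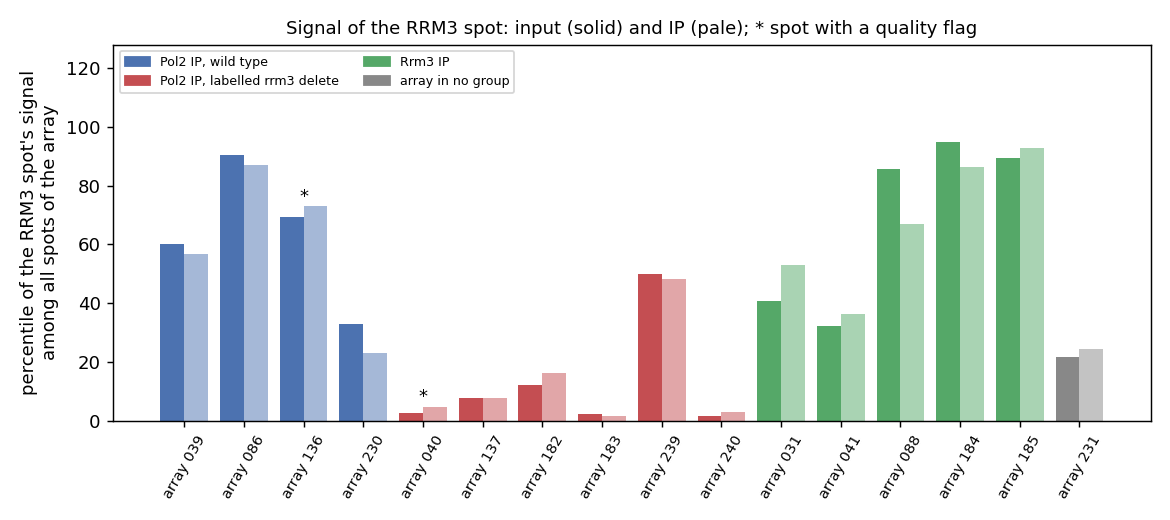
Percentile of the RRM3 spot's background-subtracted signal among all spots of each array, for input (solid bars) and IP (pale bars). Arrays labelled rrm3 delete lie at 16.2 or below except array 239, at 50.1 and 48.1.

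The Pol2 IP in wild type asks where the polymerase associates in otherwise normal cells. Genes of glycolysis and fermentation, translation factors and ribosomal proteins had list medians of 0.77, 0.46 and 0.25, above the array median at a preset correlation, with adjusted p = 0.134, 0.152 and 0.249 with an estimated correlation. TEF2, which encodes translation elongation factor 1 alpha, had a log2 ratio of 1.45 ± 0.24 (SE, n = 4; 2.73-fold). The ribosomal protein gene RPL3 had 1.32 ± 0.31 (n = 3), PDC1, the main pyruvate decarboxylase gene, 1.27 ± 0.18 (n = 4), CAR2, the ornithine transaminase gene of arginine breakdown, 1.27 ± 0.18 (n = 3) and the cell wall protein gene CCW12 1.22 ± 0.16 (n = 4). SWH1, an oxysterol-binding protein gene, PET122, needed for mitochondrial translation, LDB7, of a chromatin remodeller, YAR040C and the intergenic regions IYPL250C and IYOL005C lay between 1.22 and 1.33. ORFs named for the silent mating cassettes were below the median, HMRA1 at -1.27 ± 0.18 (n = 4) and HMLALPHA2 at -1.12 ± 0.19 (n = 4). So was the Ty1 element feature YGRCTY1-2A at -1.39 ± 0.16 (n = 4). Whether these spots share sequence with other loci was not examined. The sizes above depend on the direction of array 136, whose label its correlations with other arrays argue against. With it as labelled, TEF2 (0.75), PDC1 (0.37), CCW12 (0.60), PET122 (0.75), HMRA1 (-0.85), HMLALPHA2 (-0.58) and YGRCTY1-2A (-0.81) did not pass, the smallest adjusted p being 0.341. CAR2 and SWH1, not measured on that array, passed (0.00905 and 0.0242), while RPL3, LDB7, YAR040C, IYPL250C and IYOL005C, also not measured on it, did not (0.0961 to 0.142).

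By list, all 15 genes of glycolysis and fermentation had positive values in wild type (median 0.77), 2 of them (PDC1 and ADH1) past the threshold over all features and 11 adjusted over the list alone. Their shift had an adjusted p of 8.37e-10, and adjusted p = 0.134 with an estimated correlation. Translation factor genes had a median of 0.46 (3 of 11 higher, TEF2, HYP2 and YEF3, and 4 over the list alone), with an adjusted p of 1.06e-05, and adjusted p = 0.152 with an estimated correlation. For ribosomal protein genes the median was 0.25, with 6 of 127 higher (RPL8B at 0.93 ± 0.15) and 12 over the list alone, an adjusted p of 1.64e-07, and adjusted p = 0.249 with an estimated correlation. Cell surface protein genes (median 0.58; CCW12 and the proton pump gene PMA1, 1.02 ± 0.22, of 9 higher), chaperone genes (0.48; SSA2, an Hsp70 gene, 0.84 ± 0.16, of 10 higher) and rDNA features (0.51; 0 of 13) were shifted up at adjusted p of 9.31e-06, 0.000116 and 0.00199. With an estimated correlation their adjusted p = 0.0557, 0.123 and 0.375. The rDNA median was above 0 on 2 of the 4 arrays, running from -0.03 to 1.20, and from 0.34 to 0.93 over alternatives. The shifts below the median held with an estimated correlation for 3 lists. LTR and Ty features had a median of -0.38 (36 of 162 lower, 56 over the list alone), with adjusted p of 4.54e-17 and 0.000840 in the preset and estimated test. The silent mating locus ORFs had -1.06 (3 of 4 lower), with 4.09e-07 and 0.00114, the latter with a correlation estimated from 3 members. Meiosis and sporulation genes had -0.20 (0 of 32 lower, 2 adjusted over the list alone), with 0.01004 and 0.0107. Their estimate was negative, so the estimated test was laxer there than the preset one. ORFs were slightly higher (0.05, adjusted p 0.0142) and intergenic regions slightly lower (-0.03, 0.0321), and regions beside centromeres lower (-0.18, 0.0495), none of which held with an estimated correlation (adjusted p = 0.0790, 0.123 and 0.0907). The tRNA gene features had a median of -0.00 (adjusted p 0.827), with 1 of 41 higher, the valine tRNA gene TV(UAC)B at 0.66 ± 0.17 (n = 4). Of these single features, ADH1, HYP2, YEF3, RPL8B, PMA1, SSA2 and TV(UAC)B did not pass with array 136 as labelled (smallest adjusted p 0.494). Centromere features (0.22), histone genes (0.30) and telomere features (0.29) did not pass (adjusted p 0.0628, 0.0865 and 0.0703). Among mitochondrial DNA features INTQ0185A was at -3.45 ± 0.26, Q0190A at -2.84 ± 0.21 and Q0185D at -2.56 ± 0.24 (each n = 4), or -1.50, -1.51 and -1.31 with array 136 as labelled, where none passed (smallest adjusted p 0.456), while the list's median was 0.29 and its mean -0.04, with 1 of 76 higher and 10 lower.

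In the limma fit, 116 features were higher and 293 lower than the array median in wild type. The same sign on every array was found for 115 of the 116 and 293 of the 293 with array 136 as used, and for 48 and 95 with it as labelled. On the other 3 arrays it was found for 115 and 293. These features were chosen by the fit with array 136 as used, and 67 and 198 of them were measured on it. Turning that array ends the shared sign of those by construction, so the lower counts do not bear on its direction. Without array 039, 086, 136 or 230 the higher count was 10, 27, 58 or 27, and without array 031 of the Rrm3 IP, which enters the same fit, 439. It was 75 without a dye term, 0 with forward arrays alone (1070 at an unadjusted p under 0.05), 54 without arrays 136 and 182 and 502 without arrays 031 and 041. With array 136 turned as labelled, 5 were higher and 28 lower, chosen by that fit and all with the same sign on every array. The medians were then 0.51 for glycolysis and fermentation genes, 0.16 for ribosomal protein genes, -0.31 for LTR and Ty features and -0.71 for the silent mating loci (adjusted p 5.81e-06, 1.90e-05, 1.92e-12 and 0.000765). They were 0.26 for chaperone genes, 0.53 for cell surface protein genes, 0.42 for translation factor genes and 0.35 for rDNA features (0.0495, 0.00113, 0.00662 and 0.000290). In that direction centromere features (0.24), telomere features (0.30) and mitochondrial DNA (0.33) passed, at adjusted p of 0.0125, 0.0122 and 2.61e-05. ORFs (0.01), intergenic regions (-0.01) and regions beside centromeres (-0.18) did not, at 0.348, 0.373 and 0.130. Leaving out 1 array ended the shift of ORFs (136, adjusted p 0.0762), of intergenic regions (136 or 230, up to 0.118) and of regions beside centromeres (039, 086, 136, 137, 239 or 088, up to 0.106). It brought centromere features past the threshold (136, 230, 183, 041, 184 or 185, down to 0.0133), and likewise telomere features (136, 0.0314), histone genes (031, 0.0140) and arm ends (039 or 086, down to 0.0289). Among the other alternatives, the shifts of ORFs and intergenic regions ended without background subtraction, with no spot filter or without arrays 136 and 182 (up to 0.151 and 0.196), that of intergenic regions also with failed PCR products left out (0.0509). That of regions beside centromeres ended with other background corrections, no spot filter, either form of the deposited table, the other variance model or without arrays 136 and 182 (up to 0.306). With forward arrays alone telomere features (0.60), subtelomeric ORFs (0.13) and mitochondrial DNA (-0.22, of opposite sign) passed, at adjusted p of 3.14e-05, 3.79e-05 and 8.30e-09. With failed PCR products left out mitochondrial DNA passed at 0.21 (4.61e-06). Centromere features passed without background subtraction, with no spot filter, the uncentred deposited table or without arrays 136 and 182 (down to 0.00437), and arm ends with the first 2 of these (down to 0.0171). Histone genes passed with loess, no spot filter or without arrays 031 and 041 (down to 0.0187), and telomere features with loess, no dye term or without arrays 136 and 182 (down to 0.0313).

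On the arrays labelled rrm3 delete, the Pol2 IP was above the array median at nearly all tRNA genes and at many chromosome ends. Of 41 tRNA gene features, 39 were higher, with a list median of 0.85. The valine tRNA genes TV(CAC)D and TV(UAC)B had log2 ratios of 1.62 ± 0.13 (SE, n = 6; 3.08-fold) and 1.56 ± 0.14 (n = 6). The regions beside tRNA genes had a median of 0.47, with 115 of 238 higher and 7 lower, among them ITV(UAC)D at 1.48 ± 0.12 (n = 6) and ITF(GAA)B at 1.25 ± 0.12 (n = 6). The telomere features had a median of 0.82 (6 of 8 higher, TEL15R-1 at 1.76 ± 0.17, n = 5). The largest ratios the rule names were at chromosome ends: IYLR461W-0, a region by its name near the right end of chromosome XII, at 2.18 ± 0.15 (n = 4; 4.53-fold), YDR543C at 1.99 ± 0.19 (n = 5), IYPL283C-1 at 1.89 ± 0.14 (n = 6) and YNL337W at 1.87 ± 0.18 (n = 5). IYDR543C, IYBL109W-0, IYAL069W, YAL069W, CAR2 and IYERWOMEGA2-0, beside an LTR, lay between 1.79 and 1.83.

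Glycolysis and fermentation genes had a median of 0.79 (11 of 15 higher, 12 adjusted over the list alone, PDC1 at 1.24 ± 0.15), with an adjusted p of 3.93e-07, and adjusted p = 0.206 with an estimated correlation. Translation factor genes had a median of 0.53 (5 of 11 higher, HYP2, which encodes translation factor eIF5A, 0.87 ± 0.12), with 0.000398, and adjusted p = 0.231 with an estimated correlation. The medians were 0.65 for cell surface protein genes (5 of 9 higher, CCW12 at 1.11 ± 0.13) and 0.20 for ribosomal protein genes (19 of 127 higher, 3 lower, RPL8B at 0.97 ± 0.12). They were 0.26 for chaperone genes (2 of 10 higher) and 0.41 for rDNA features (4 of 13 higher, the 5S gene RDN5-1 at 1.46 ± 0.23). Adjusted p of these 4 lists was 0.000227, 0.00295, 0.0222 and 0.00189 in that order. With an estimated correlation adjusted p = 0.106, 0.515, 0.358 and 0.375. The rDNA median ran from -0.23 to 1.13 over the arrays, above 0 on 5 of 6, and from 0.25 to 0.90 over alternatives. Subtelomeric ORFs (median 0.20, 47 of 233 higher), the ORFs and regions at the ends of chromosome arms (0.14, 111 of 533 higher, 27 lower) and snRNA and snoRNA features (0.25, 7 of 43 higher; the snoRNA gene SNR52 0.75 ± 0.12) also shifted up, at adjusted p of 4.26e-06, 9.05e-06 and 0.00789. With an estimated correlation adjusted p = 0.206, 0.206 and 0.199. LTR and Ty features (-0.24, 41 lower and 13 higher of 162) and the silent mating loci (-0.62, 2 of 4 lower) shifted down at adjusted p of 0.000125 and 0.0318, and with an estimated correlation adjusted p = 0.134 and 0.185. The 3 shifts that held with an estimated correlation were tRNA genes, the regions beside them and telomere features (adjusted p 0.000840, 0.000840 and 0.0119). The correlation of telomere features was estimated from 5 members. Histone genes (0.04), meiosis and sporulation genes (-0.15, 8 of 32 lower), galactose genes (-0.19), centromere features (0.21), the regions beside centromeres (-0.14) and mitochondrial DNA (median 0.30, mean -0.07) did not pass.

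In all, 1166 features were higher and 854 lower on the arrays labelled rrm3 delete, and 1035 and 764 of these had the same sign on every array. Without array 040 or 031 the higher count was 750 or 1803, with forward arrays alone 353, and with array 136 as labelled 1033. With array 136 as labelled the shifts of chaperone genes (0.27) and the silent mating loci (-0.63) did not pass, at adjusted p of 0.0649 and 0.130. The latter was also lost without array 040, 240 or 031 (up to 0.0609), while meiosis and sporulation genes passed without array 183 (0.0493) and regions beside centromeres without array 185 (0.0393). The silent mating locus shift also ended with normexp, with dim spots left out or without arrays 031 and 041 (up to 0.122), and that of chaperone genes without background subtraction (0.0650). With forward arrays alone the shifts of chaperone genes and snRNA and snoRNA features did not pass (adjusted p 0.0503 for each), while mitochondrial DNA did at -0.21 (3.15e-09), of opposite sign, and ORFs next to a tRNA gene at 0.13 (0.0361). With failed PCR products left out mitochondrial DNA passed at 0.28 (0.000150). Meiosis and sporulation genes also passed then, without background subtraction or without arrays 031 and 041 (down to 0.0276), and centromere features without background subtraction or with no spot filter (down to 0.0306).

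The Rrm3 IP asks where the helicase itself associates. YEF3, which encodes translation elongation factor 3, had a log2 ratio of 1.63 ± 0.15 (SE, n = 5; 3.09-fold), the phosphate transporter gene PHO84 1.58 ± 0.15 (n = 5), RPL3 1.56 ± 0.24 (n = 5), the cell wall protein gene HPF1 1.61 ± 0.22 (n = 4) and MTC7 1.61 ± 0.21 (n = 5). The 25S rDNA features RDN25-1 and RDN25-1B, at 1.65 ± 0.32 and 1.63 ± 0.31 (each n = 5), and the intergenic regions IYPR080W (1.73 ± 0.23, n = 5), IYJL156C (1.56 ± 0.46, n = 4) and IYOL097C (1.55 ± 0.47, n = 4) complete the 10 largest. Histone genes, snRNA and snoRNA genes, centromeres and ribosomal protein genes were above the median as groups. Of 8 histone genes 5 were higher (median 0.77, the histone H4 gene HHF2 1.01 ± 0.22 and the histone H2B gene HTB2 0.89 ± 0.20). Of 43 snRNA and snoRNA features 18 were higher (0.50, SNR64 0.75 ± 0.13, 25 adjusted over the list alone). Of 14 centromere features 9 were higher (0.54, CEN11 0.66 ± 0.14, n = 5, 13 over the list alone). Of 127 ribosomal protein genes 65 were higher (0.53, RPL10 1.34 ± 0.16, 76 over the list alone). Adjusted p was 0.000586, 8.37e-10, 1.05e-05 and 8.89e-22, and 0.00195, 0.00195, 0.00204 and 0.0466 with an estimated correlation. For centromere features that correlation was estimated from 4 members. Meiosis and sporulation genes were below the median (-0.33, 12 of 32 lower and 4 higher; the meiotic kinase gene MEK1 at -1.19 ± 0.21). Their adjusted p was 0.0172, and 0.0188 with an estimated correlation. For these and for histone genes the estimate was negative, so the estimated test was laxer than the preset one.

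Glycolysis and fermentation genes (median 0.94, 12 of 15 higher), translation factor genes (0.71, 6 of 11), cell surface protein genes (0.76, 5 of 9), chaperone genes (0.39, 3 of 10), rDNA features (0.88, 10 of 13) and mitochondrial DNA features (0.66, 48 of 76 higher, 3 lower) passed at adjusted p of 3.87e-09, 1.37e-07, 5.16e-05, 0.00235, 2.53e-06 and 4.34e-13. With an estimated correlation adjusted p = 0.152, 0.0910, 0.0883, 0.206, 0.185 and 0.173. For glycolysis and fermentation, translation factor, cell surface protein and chaperone genes array 031 was lowest, at -0.29, 0.06, -0.12 and -0.20. The other arrays had at least 1.03, 0.76, 0.65 and 0.23 in that order. Over alternatives these medians ran from 0.67 to 1.26, 0.51 to 1.11, 0.51 to 1.14 and 0.23 to 0.62. The rDNA median was 2.48 on array 088, against 0.38 to 0.97 on the others, and ranged from 0.58 to 1.46 over alternatives. Mitochondrial DNA medians ran from -0.04 on array 041 to 1.40 on array 184. The tRNA genes had a median of 0.32 (14 of 41 higher, 15 over the list alone; TR(UCU)M2, an arginine tRNA gene, 0.61 ± 0.12). It was -0.30 on array 031, against 0.41 to 0.55 on the others, and 0.15 to 0.51 over alternatives, highest without array 031. The regions beside them had 0.23 (57 of 238 higher, 5 lower). Adjusted p was 3.70e-06 and 3.78e-07, and adjusted p = 0.231 and 0.106 with an estimated correlation. LTR and Ty features (-0.13, 39 of 162 lower, 12 higher), the silent mating loci (-0.61, 3 of 4 lower), subtelomeric ORFs (-0.13, 38 of 233 lower, 14 higher, the thiamine synthesis gene THI11 -0.85 ± 0.12) and the ends of chromosome arms (-0.20, 121 of 533 lower, 37 higher) were below the median. Their adjusted p was 0.0222, 0.00718, 0.0215 and 0.000398, and adjusted p = 0.370, 0.104, 0.518 and 0.321 with an estimated correlation. Galactose genes (-0.36), telomere features (0.26), ORFs next to a tRNA gene (-0.10) and regions beside centromeres (-0.16) did not pass (adjusted p 0.0887, 0.0952, 0.0762 and 0.916). Of the galactose genes, GAL2 was lower at -0.42 and GAL7 at -0.74 ± 0.16, measured on 3 of the 5 arrays. With no spot filter GAL7 turned to 1.02, not past the threshold (adjusted p 0.305).

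In the Rrm3 IP 1359 features were higher and 1571 lower, of which 943 and 996 had the same sign on every array. The split depended on the centring: with the deposited table left uncentred, 775 were higher and 1835 lower. Without array 184 583 were higher, with forward arrays alone 163, and with array 136 as labelled 1162. The shift of LTR and Ty features was lost with array 136 as labelled (-0.13, adjusted p 0.0730) and without array 031 or 185 (up to 0.0731), arrays 031 and 041 (0.106), or centring of the deposited table (0.0670). That of meiosis and sporulation genes was lost without array 088 or 184 (up to 0.103) and that of subtelomeric ORFs without 041, 088 or 184 (up to 0.297). With forward arrays alone the shifts of meiosis and sporulation genes (-0.20), subtelomeric ORFs (0.04), arm ends (-0.07) and mitochondrial DNA (0.18) did not pass, at adjusted p of 0.198, 0.581, 0.127 and 0.0709, and telomere features did (0.46, 0.0122). Telomere features also passed without array 041 (0.0226), and ORFs next to a tRNA gene without 041 or 088 (down to 0.0413), without background subtraction, with no spot filter or with failed PCR products left out (down to 0.0284). Galactose genes passed without arrays 031 and 041 (-0.49, 0.0297).

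Features above the median for both proteins were counted from groups that share no array. Their calls still share a variance and a dye term per feature, because the same fit gave both. Calls in both groups can thus go together, and the numbers for independent lists are not a strict reference. Of the 116 features higher in the wild-type Pol2 IP, 80 (69.0%) were also higher in the Rrm3 IP, against 12.8 for independent lists, and 183 were lower in both, against 37.3. The features higher in both include TEF2, RPL3, PDC1, CCW12, HYP2 and YEF3. Between the wild-type Pol2 IP and the arrays labelled rrm3 delete 100 higher features were shared (10.95 for independent lists), and between those arrays and the Rrm3 IP 395 (128.3). Across features the fitted log2 values correlated at r = 0.56, 0.69 and 0.46 in the same order, and features are not independent replicates. With array 136 as labelled 5 features were higher in both the wild-type Pol2 and Rrm3 IP, against 0.470, with forward arrays alone 0, and without array 039, 086, 136, 230 or 031 the count was 10, 25, 46, 26 or 294.

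**Figure D2:**
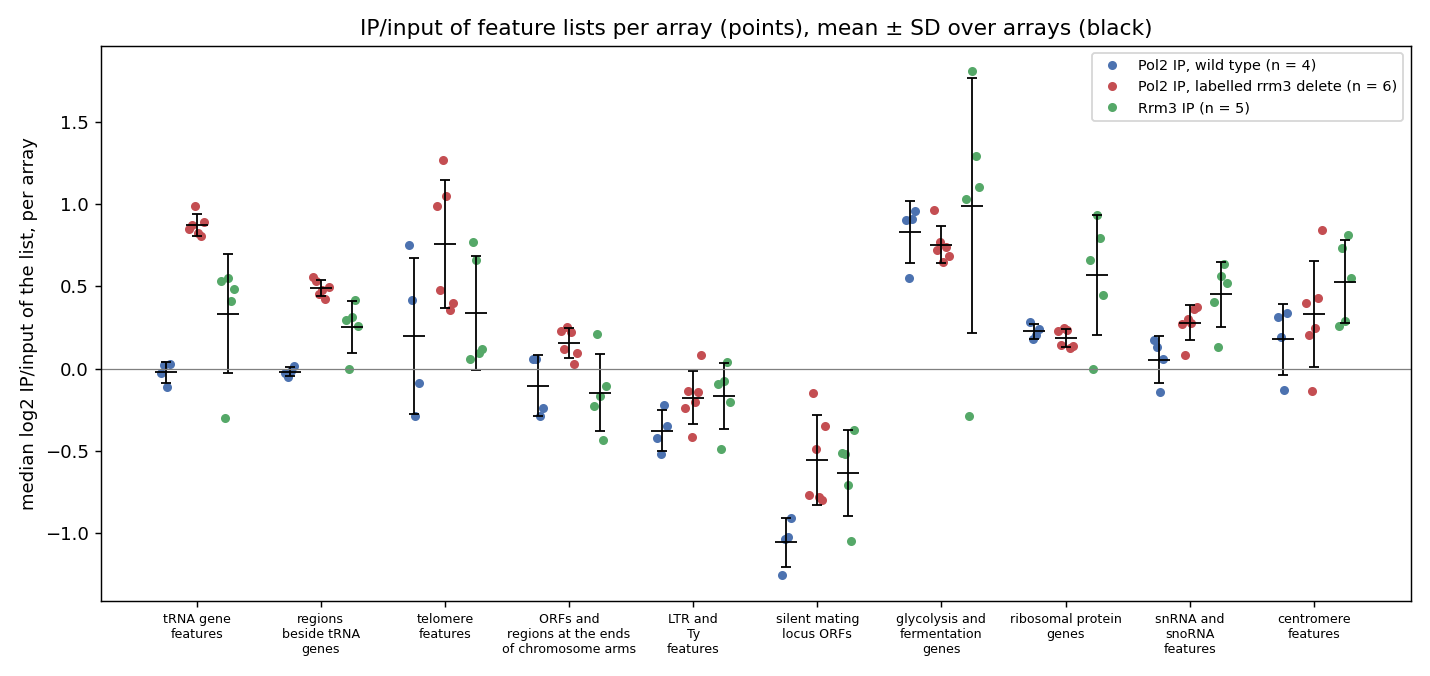
Median log2 IP over input of 10 feature lists on each array (points), with the mean and SD over arrays (black) for the Pol2 IP in wild type (n = 4), the Pol2 IP labelled rrm3 delete (n = 6) and the Rrm3 IP (n = 5). The tRNA gene medians lie at 0.81 to 0.99 on the arrays labelled rrm3 delete and at -0.11 to 0.03 in wild type.

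Comparing both sets of Pol2 arrays asks whether association of the polymerase differs with RRM3. The tRNA gene features were higher on the arrays labelled rrm3 delete by a median of 0.91, and all 41 had a positive difference, 8 past the threshold over all features and 34 adjusted over the list alone. TV(CAC)D went from -0.02 ± 0.16 (SE, n = 4) in wild type to 1.62 ± 0.13 (n = 6), a difference of 1.64 ± 0.21 (3.13-fold). The asparagine tRNA gene TN(GUU)C differed by 1.07 ± 0.20 and the lysine tRNA gene TK(CUU)P by 1.01 ± 0.18. The regions beside tRNA genes were higher by a median of 0.49, with 223 of 238 differences positive, 10 past the threshold and 49 over the list alone, for example ITA(UGC)A (1.24 ± 0.21), ITF(GAA)B (1.21 ± 0.20) and ITV(AAC)E2 (1.04 ± 0.19). At the chromosome ends, 27 of 533 ORFs and regions of the arm ends were higher, together with the telomere features TEL15R-1 (1.53 ± 0.26) and TEL6R (0.93 ± 0.20). IYLL065W, by its name near the left end of chromosome XII, differed by 1.97 ± 0.21 (adjusted p 0.000838; -0.21 in wild type and 1.75 on the arrays labelled rrm3 delete), IYAL069W by 1.95 ± 0.25 and IYPL283C-1 by 1.87 ± 0.23. Further arm-end differences were those of IYLR461W-0 (1.81 ± 0.23), YDR543C (1.80 ± 0.28), IYNR076W (1.75 ± 0.27) and YAL069W (1.67 ± 0.26). The ORF REE1 (1.44 ± 0.26) is a further arm-end feature. With array 136 as labelled these 3 regions differed by 1.98, 1.65 and 1.71 (adjusted p 0.00115, 0.00902 and 0.00496), YDR543C by 2.02 (0.00621) and TV(CAC)D by 1.55 (0.00496), while TEL6R (0.83), TK(CUU)P (0.90) and REE1 (1.29) did not pass (0.128, 0.0538 and 0.0516).

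Other features past the threshold lay mostly elsewhere. The ribosome biogenesis gene TMA23 differed by 1.67 ± 0.23, LSM3, of an RNA-binding ring complex, by 1.30 ± 0.20, the phosphate transporter gene PHO87 by 1.22 ± 0.22, the palmitoyltransferase gene PFA3 by 1.21 ± 0.22 and the cell wall gene DAN4 by 0.75 ± 0.16. PHO87, PFA3 and DAN4 were named after their values were seen, as the remaining ORFs of that group of 5. The LTR features YERWOMEGA2 (1.49 ± 0.28) and YERWDELTA17 (0.88 ± 0.18) and the region IYERWOMEGA2-0 (1.65 ± 0.26) were higher. So were 3 of 432 ORFs next to a tRNA gene (YER181C, YGR164W and MRPS8, a mitochondrial ribosomal protein gene) and 12 intergenic regions outside these classes, IYERWOMEGA2-0 among them. Of these, YGR164W, MRPS8 and YERWDELTA17 did not pass with array 136 as labelled (adjusted p 0.0703, 0.187 and 0.0803).

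**Figure D3:**
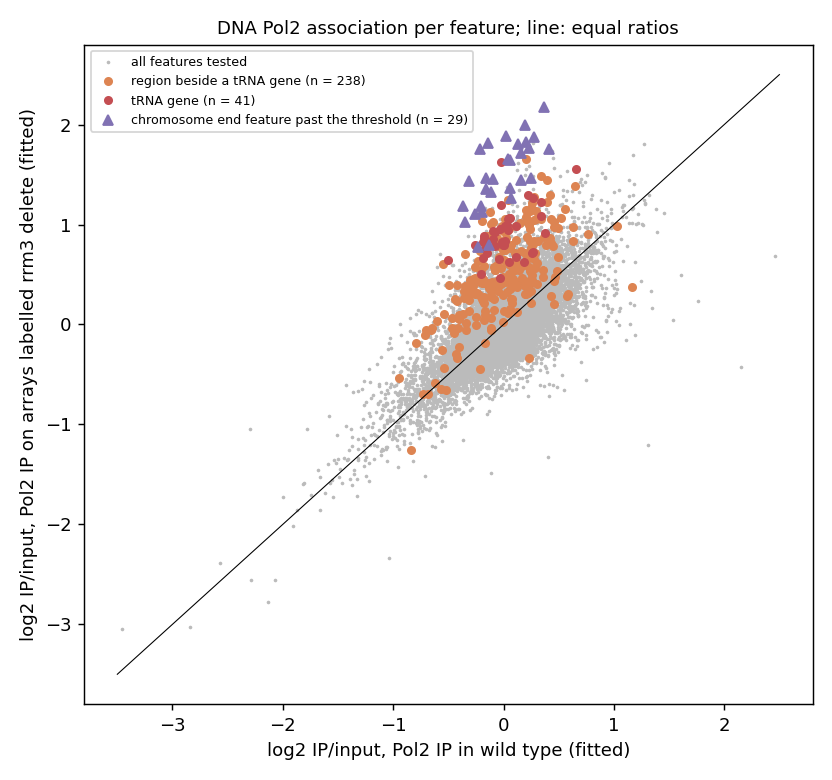
Fitted log2 IP over input of each of 12350 features in the wild-type Pol2 IP (horizontal) and on arrays labelled rrm3 delete (vertical), with tRNA genes (red, 41), regions beside them (orange, 238) and chromosome end features past the threshold (triangles) marked. All 41 tRNA genes lie above the line of equal ratios, by a median of 0.91.

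By limma, 69 features were higher and 0 lower on the arrays labelled rrm3 delete than in wild type (675 at an unadjusted p under 0.05). For 64 of the 69, which were chosen for their difference, the groups did not overlap (56 with array 136 as labelled). Random grouping of 4 against 6 arrays separates 0.476% of features 1 way, and more of those measured on fewer arrays. The list shifts of tRNA genes (adjusted p 6.76e-63, and 4.30e-06 with an estimated correlation), regions beside them (6.06e-45 and 1.14e-06), telomere features (median 0.50; 2.56e-06 and 0.0207) and arm ends (median 0.21, 408 of 533 positive; 4.54e-17 and 0.0188) held in both tests. Regions beside tRNA genes, telomere features and arm ends were listed after the data were seen, which makes their tests descriptions rather than independent evidence. The correlation of telomere features was estimated from only 5 members. Over arrays, the tRNA gene medians were -0.02 ± 0.06 (SD, n = 4) in wild type and 0.87 ± 0.07 (SD, n = 6) on arrays labelled rrm3 delete, positive on 6 of 6, with an exact permutation p of 0.00952, the smallest that 210 splits allow (adjusted 0.110 over 46 such tests). The same test gave an exact p of 0.00952 (adjusted 0.110) for regions beside tRNA genes, the silent mating loci and galactose genes, and 0.0286 (adjusted 0.162) for arm ends, snRNA and snoRNA features and chaperone genes. For telomere features it gave 0.0857 (adjusted 0.219), with overlapping arrays, -0.29 to 0.75 in wild type and 0.36 to 1.27 on arrays labelled rrm3 delete. These permutations pooled both dye orientations. The wild-type telomere median moved with orientation, from 0.29 in the main fit to 0.60 with forward arrays alone. Array 239, with RRM3 signal, had a tRNA gene median of 0.82.

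Further lists passed the preset test alone. Subtelomeric ORFs were higher by a median of 0.18 (1 of 233 past the threshold, 4 over the list alone), LTR and Ty features by 0.20 (2 of 162), the silent mating locus ORFs by 0.42 (0 of 4), snRNA and snoRNA features by 0.17 (0 of 43) and ORFs next to a tRNA gene by 0.07 (3 of 432, 4 over the list alone). Their adjusted p was 6.98e-06, 1.05e-05, 0.00772, 0.0225 and 0.0290, and with an estimated correlation adjusted p = 0.212, 0.0923, 0.106, 0.258 and 0.3998. Ribosomal protein genes were lower by a median of -0.05 (adjusted p 0.0434, and adjusted p = 0.671 with an estimated correlation) and galactose genes by -0.33 (0.0222, too few complete members for an estimate). Glycolysis and fermentation genes differed by -0.00, translation factor genes by -0.03, cell surface protein genes by 0.05, chaperone genes by -0.17, histone genes by -0.18, meiosis and sporulation genes by 0.04, rDNA features by 0.14, centromere features by 0.01, regions beside centromeres by 0.08 and mitochondrial DNA by -0.03, none past the threshold. With array 136 as labelled the silent mating loci differed by 0.21 (adjusted p 0.268) and ribosomal protein genes by 0.01 (0.673), neither past the threshold, LTR and Ty features by 0.11 (0.0261), and mitochondrial DNA passed at -0.04 (0.0247). Leaving out 1 array ended the shifts of ribosomal protein genes (039, 136, 230, 183, 240 or 184, up to 0.124), ORFs next to a tRNA gene (039, 086, 183 or 137, up to 0.179), galactose genes (230 or 137, up to 0.0886) and snRNA and snoRNA features (230 or 239, up to 0.140). It brought mitochondrial DNA (086, 0.0299) and histone genes (031, 0.0401) past the threshold. The galactose shift was also lost without background subtraction (0.0891) and with no spot filter (0.0725). Without background subtraction and with forward arrays alone the shifts of ribosomal protein genes (0.112 and 0.541) and of snRNA and snoRNA features (0.0747 and 0.175) did not pass. That of ribosomal protein genes was also lost with the uncentred deposited table (0.0761) or without arrays 136 and 182 (0.102). Centromere features passed with forward arrays alone (-0.09, 0.0396), mitochondrial DNA without arrays 136 and 182 (0.0134) and histone genes without arrays 031 and 041 (0.0489).

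Probes of tRNA genes and of chromosome ends share sequence with other copies, so their signal cannot be assigned to 1 copy. The count of 69 was lower without array 039 (14), 086 (9), 136 (32), 230 (8), 040 (22), 183 (18), 137 (20), 239 (19) or 240 (43) and 236 without array 031. It was 43 with array 136 as labelled and 0 with forward arrays alone (367 at an unadjusted p under 0.05). It was 38 with normexp, 37 without a dye term, 21 with the uncentred deposited table, 23 without arrays 136 and 182 and 244 without arrays 031 and 041. The tRNA gene shift stayed between 0.82 and 0.95 and past the threshold in 30 of 30 alternatives (0.86 with array 136 as labelled).

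Setting the Rrm3 IP against the wild-type Pol2 IP, which shares its 4 arrays with the comparison of Pol2 arrays, asks where the proteins associate differently. A mitochondrial feature, 21S_RRNA0 of the large ribosomal RNA gene, was the 1 feature past the threshold. It rose from -1.32 ± 0.15 (SE, n = 4) in the Pol2 IP to 0.19 ± 0.15 (n = 4) in the Rrm3 IP, a difference of 1.51 ± 0.21 (adjusted p 0.0304). As groups, snRNA and snoRNA features were higher in the Rrm3 IP by a median of 0.36 (39 of 43 positive, 5 over the list alone; adjusted p 1.22e-09, and 0.00204 with an estimated correlation), and centromere features by 0.31 (13 of 14 positive, 1 over the list alone; 0.00154 and 0.0385). ORFs were lower by -0.07 (0.000467 and 0.00806). Over arrays, exact permutation p was 0.0476, 0.0952 and 0.0794 for these 3 lists (adjusted 0.215, 0.219 and 0.215), and centromere medians overlapped, -0.13 to 0.34 in the Pol2 IP and 0.26 to 0.81 in the Rrm3 IP. The smallest in this comparison was 0.0159, for galactose genes (adjusted 0.146). Members with the smallest adjusted p did not pass alone, such as SNR66 at 0.86 ± 0.22 (adjusted p 0.271) and CEN4 at 0.79 ± 0.22 (0.290). The correlation of centromere features was estimated from only 4 members.

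Mitochondrial DNA features (median 0.47, 72 of 76 positive), ribosomal protein genes (0.23, 111 of 127), tRNA genes (0.36, 38 of 41), regions beside tRNA genes (0.28, 200 of 238), LTR and Ty features (0.28, 122 of 162) and subtelomeric ORFs (-0.21, 65 of 233) passed the preset test at adjusted p of 1.16e-17, 1.05e-08, 4.73e-07, 7.01e-10, 4.93e-07 and 4.41e-05. With an estimated correlation adjusted p = 0.110, 0.206, 0.206, 0.0537, 0.0546 and 0.258. Over alternatives their medians ran from 0.30 to 0.57, 0.08 to 0.47, 0.15 to 0.52, 0.12 to 0.35, 0.11 to 0.31 (0.16 with array 136 as labelled) and -0.34 to -0.10. Galactose genes (-0.43; 0.00708), histone genes (0.40; 0.0440), rDNA features (0.42; 0.0238), translation factor genes (0.25; 0.0308), arm ends (-0.11; 0.0178), ORFs next to a tRNA gene (-0.08; 0.0314) and intergenic regions (0.05; 0.0142) also passed. With an estimated correlation adjusted p = 0.0910 for histone genes, 0.515 for rDNA, 0.476 for translation factors, 0.501 for arm ends, 0.403 for ORFs next to a tRNA gene and 0.0880 for intergenic regions. The other 7 lists did not pass, among them glycolysis and fermentation genes (0.07) and telomere features (0.03). Glycolysis and fermentation genes passed without array 031 (0.40, adjusted p 6.14e-06) and with array 136 as labelled (0.31, 0.0240), and ranged from -0.17 to 0.52 over alternatives. Without array 031 cell surface protein genes also passed (0.000382), as did regions beside centromeres without 230 or 088 (down to 0.0204), with forward arrays alone (0.0268) or with dim spots left out (0.0370), and the silent mating loci without 184 (0.0350). Leaving out 1 array ended the shifts of histone genes (039, 086, 041, 088 or 185, up to 0.162), translation factor genes (086, 136, 041, 088, 184 or 185, up to 0.298), rDNA (086, 136, 230, 088 or 185, up to 0.497), arm ends (039, 041, 088 or 184, up to 0.226), ORFs next to a tRNA gene (136, 230, 031 or 184, up to 0.273) and intergenic regions (136 or 184, up to 0.211). With array 136 as labelled ORFs next to a tRNA gene (-0.07, 0.130) and intergenic regions (0.04, 0.223) did not pass, and with no spot filter galactose genes did not (-0.28, adjusted p 0.290). Forward arrays alone ended the shifts of translation factor genes (0.240), rDNA (0.566), ORFs next to a tRNA gene (0.688) and intergenic regions (0.368). The rDNA shift was also lost without background subtraction, with normexp, loess or no dye term, and that of histone genes with loess, no dye term or no spot filter (up to 0.122 and 0.0611). That of ORFs next to a tRNA gene was lost with loess or no spot filter (up to 0.0611). Without arrays 136 and 182 the shifts of translation factor genes, histone genes, rDNA, intergenic regions and ORFs next to a tRNA gene did not pass (up to 0.0841). Without arrays 031 and 041 glycolysis and fermentation (8.99e-06), cell surface protein (0.000174) and meiosis and sporulation genes (-0.13, 0.0200) passed, and ORFs next to a tRNA gene did not (0.0521).

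By limma 1 feature was higher and 0 lower in the Rrm3 IP than in the wild-type Pol2 IP (1325 at an unadjusted p under 0.05). The 1 call was lost without array 039, 086, 136, 183, 137, 239, 240, 041, 031, 184 or 185, and with array 136 as labelled, where the shift of ORFs (-0.04) also did not pass (adjusted p 0.0568). It was also lost without background subtraction, with normexp, loess, no dye term, forward arrays alone, no spot filter or the uncentred deposited table, and without arrays 136 and 182 or 031 and 041. With forward arrays alone the shifts of centromere features and ORFs did not pass (largest adjusted p 0.176 and 0.115).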

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

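The tests of dye orientation and of the label of array 239 were chosen after the result was seen, as were the lists of regions beside tRNA genes, ORFs next to a tRNA gene, telomere features and arm ends.

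The tRNA gene features were higher in the Pol2 IP on arrays labelled rrm3 delete than in wild type by a median of 0.91, a difference between groups that drew attention. Dye orientation is argued against by a difference of 0.89 on forward arrays and 0.90 on dye swaps. Array 136 was among the swaps by the direction used. With it as labelled the differences were 0.85 and 0.83, which leaves 1 wild-type swap. Spot brightness is argued against by random lists matched on it, of which 0 of 10000 reached the median (highest 0.23). Their p of 0.0001, the smallest such draws can give, came from drawing features, not from permuting arrays. Drawn features were treated as independent, while the tRNA gene features had an estimated correlation of 0.33, so that p may be too small. Among 100 of the 210 possible splits of the arrays 1, the real one, gave 69 or more features, with 3 in the highest other. A random split of independent arrays thus rarely reached that count. The remaining splits were not tried, and dye swaps sharing an extract may not be independent. The tRNA gene median reached 0.68 in another split. Its exact test over arrays gave p = 0.00952, the smallest that 210 splits allow. Adjusted over 46 such tests it was 0.110, and that floor limits what the adjusted value can show. Signal shared between copies of tRNA genes stays open: ORFs next to a tRNA gene differed by a median of 0.069, with an adjusted p of 0.0290 and adjusted p = 0.3998 with an estimated correlation, and the length of the DNA fragments, which sets whether such ORFs may show a neighbour's signal, is not given in the sources used here. The regions beside tRNA genes, which are separate spots, differed by a median of 0.49, with 223 of 238 positive. Whether those regions share sequence with other copies was not examined, so they do not settle it. A biological difference between the groups, the deletion that the labels name, stays open and was not tested.

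Glycolysis, translation factor and ribosomal protein genes had medians above 0 in all 3 groups, except that on array 031 of the Rrm3 IP glycolysis genes had -0.29 and ribosomal protein genes -0.00. In wild type these shifts have adjusted p = 0.134, 0.152 and 0.249 with an estimated correlation. A trend of the ratio with spot brightness is argued against by loess, which left wild-type medians of 0.81, 0.51 and 0.28. Capture of strongly transcribed genes in any immunoprecipitation cannot be told apart from association of the tagged proteins, because there were 0 arrays of an immunoprecipitation without the tag. No biological explanation was tested.

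The RRM3 signal on array 239, labelled rrm3 delete, lay at percentiles 50.1 and 48.1. Its tRNA gene median was 0.82, against -0.11 to 0.03 on the wild-type arrays and 0.81 to 0.99 on the other 5 arrays of its group. That argues against an exchange with the wild-type Pol2 samples. It cannot decide whether the DNA carried the deletion, because the link of the tRNA gene signal to the deletion was not tested. What gave the RRM3 signal there stays open.

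The regions beside tRNA genes differed between the Pol2 groups by a median of 0.49, telomere features by 0.50 and the ends of chromosome arms by 0.21. Single arrays stood apart from the rest of their group in 5 of 69 groups tested, where chance gives 3.45. Glycolysis and fermentation genes had a median of 0.55 on wild-type array 086, against 0.90 to 0.96 on the others. Cell surface protein genes had 0.25 on wild-type array 136, against 0.57 to 0.61. The tRNA genes had -0.30 on array 031 of the Rrm3 IP, against 0.41 to 0.55. The rDNA features had 2.48 on array 088 of the Rrm3 IP, against 0.38 to 0.97. The snRNA and snoRNA features had 0.080 on array 183, labelled rrm3 delete, against 0.27 to 0.38. On the unassigned array 231, which enters no comparison, the ends of chromosome arms had a median of 0.15. Wild-type arrays spanned -0.29 to 0.06 and the arrays labelled rrm3 delete 0.02 to 0.25.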

How the results depend on the processing

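Array 136 as labelled, arrays 136 and 182 or 031 and 041 left out, failed PCR spots left out and the uncentred deposited table were chosen after the result was seen. The higher tRNA gene features on arrays labelled rrm3 delete than in wild type stayed past the threshold in 30 of 30 alternatives (0.82 to 0.95), as did the regions beside them (0.38 to 0.57), telomere features (0.40 to 0.64) and arm ends (0.16 to 0.25). The counts of features moved more, and the causes were not tested unless fewer arrays explain them. The 116 features higher in the wild-type Pol2 IP became 75 without a dye term, 0 with forward arrays alone, 5 with array 136 as labelled, 54 without arrays 136 and 182, 502 without arrays 031 and 041, and 10 to 439 when leaving out each array. The 1166 on arrays labelled rrm3 delete became 353 with forward arrays alone, 1896 without arrays 031 and 041 and 750 to 1803 leaving out each array. The 1359 of the Rrm3 IP became 163 with forward arrays alone, 775 uncentred, 884 at 1.5-fold or more and 583 to 1544 leaving out each array. The 80 shared by the wild-type Pol2 and Rrm3 IP became 53, 0, 5, 42 and 321 in the order given for wild type, and 10 to 294. The 69 differing between the Pol2 groups became 38 with normexp, 37 without a dye term, 0 with forward arrays alone, 21 uncentred, 43 with array 136 as labelled, 23 and 244 without those pairs of arrays, and 8 to 236. The 1 differing between Rrm3 and wild-type Pol2 IP became 2 with failed PCR spots left out, stayed 1 with dim spots left out, with the centred deposited table and with a trended robust variance, was 0 without background subtraction, with normexp, loess, no dye term, forward arrays alone, no spot filter, the uncentred deposited table, array 136 as labelled or either pair of arrays left out, and was 0 to 1 leaving out each array. As many features came up in 6 of 100 splits of those arrays, with 11 in the highest, so chance is not excluded for it. Of 70 list shifts past the threshold, 18 stayed with an estimated correlation. GAL7 in the Rrm3 IP reversed from -0.74 to 1.02 with no spot filter. A block for scan or print batch was not run. Signal over background was 1.74 to 9.60 and 2.74 to 20.97 in the channels.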

Other observations

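Array 231, which the labels place both with and without the deletion, was measured once. Its RRM3 feature lay at percentile 21.7 in the input and 24.4 in the IP. Its tRNA genes had a median of -0.17, the regions beside them -0.18, telomere features 0.60, glycolysis and fermentation genes 0.44, ribosomal protein genes 0.15, LTR and Ty features -0.55 and the silent mating locus ORFs -0.67. Across features it correlated with wild-type arrays at a median r of 0.38, with arrays labelled rrm3 delete at 0.45 and with the Rrm3 IP at 0.12. Array 231 is a dye swap, and these values followed orientation. With other arrays labelled dye swaps r was 0.48 to 0.56, and with arrays labelled forward 0.11 to 0.41. Within the Rrm3 IP the swaps 184 and 185 gave 0.48 each and the forward arrays 0.11 to 0.12. The medians therefore do not place array 231 with a group.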
